A study of Caenorhabditis elegans with 48 samples.

How the data were processed

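Messenger RNA and ribosome footprints were sequenced from C. elegans in 48 samples, 24 per assay, and every sample in the tables was used. The counts per gene in the mRNA-seq and Ribo-seq tables were deposited as whole numbers with no scaling, one column per library. Adapters were trimmed with cutadapt, per the submitters' processing notes, with no version given; the aligner, the counting tool, the genome build and the annotation are not given in the sources used here. The mRNA-seq table held 19454 genes and the Ribo-seq table held 10741 genes. Each gene of the Ribo-seq table had at least 10 counts in at least 13 of the 24 columns. The deposited log2 values of translational efficiency (TE) covered 10700 genes, and all 256800 of them equalled the log2 of (Ribo-seq count + 1) over (mRNA-seq count + 1) of same-named columns, within 1e-09. They carried no scaling for library size, and library medians ran from -2.39 to -0.81. The TE table left out 41 genes of the Ribo-seq table, of which 12 were replication-dependent histone genes and 24 had under 10 mRNA-seq counts in at least 12 libraries. Symbols came from a reference table of gene names, which named 19414 of the 19454 identifiers; the 40 others held 0.471% to 1.18% of mRNA-seq counts. No gene coordinates were used, so overlapping and antisense genes were not examined, and the labels do not say whether counting used the strand. Group and replicate came from the labels; in the knockdown experiment the columns carry letters where the labels carry numbers, so libraries are named here by letter.

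Comparisons, tests, gene lists, the rule for named genes and most alternatives were fixed before the data were examined. Each assay was fitted with edgeR 4.0.16 in R 4.3.3: filterByExpr on the groups, TMM normalization, a robust quasi-likelihood fit with group as the only term, two-sided tests and Benjamini-Hochberg adjustment, with an adjusted p under 0.05 as the threshold. CPM are counts scaled to library size. Fed and Starved were fitted together (6 and 6 libraries per assay), and Empty_vector, E02H1.1 and C27F2.4 were fitted together (4 per group and assay), so that both knockdowns shared 1 estimate of spread. A change in TE was tested as the interaction of assay and group in 1 edgeR model over both assays, with TMM within each assay, for genes that passed the filter in both. With no spike-in named, TE and fold changes are relative to the other genes of a library. The SE of a log2 fold change was its size over the square root of the quasi-likelihood F.

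The 27 gene lists covered ribosomal proteins, translation, stress responses, metabolism, heritable small RNA pathways, immunity, stage and tissue markers. Each list was tested with camera in limma 3.58.1 on the signed gene statistics, with a preset inter-gene correlation of 0.01 and adjustment over the lists. A second camera test was run on log2 CPM, with the correlation estimated from the data, and is named here by its estimated correlation. The 2 tests also differ in their gene statistics, so a call lost in the second is not due to the correlation between members alone. Members past the threshold were counted over all genes tested and adjusted over the list alone. Named genes were the targets; for each comparison against Fed or Empty_vector, the 6 highest and 6 lowest fold changes past the threshold among genes whose 2 groups did not overlap and whose mean reached 10 CPM in either group, with at most 2 per symbol stem; and up to 2 members each way of each list. Names outside this rule are given as chosen after their values were seen.

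Overlap of the knockdowns was set beside the number from independent lists, 20 simulations of unchanged groups sharing controls, and the overlap with Empty_vector split 2 and 2. The simulation was first drawn for the knockdown groups alone, which gave no correlation by construction, and was then drawn for all 3 groups. Fold changes of Starved and of each knockdown were compared by Pearson's r across genes, with a jackknife SE over libraries. Whether same-named mRNA-seq and Ribo-seq libraries vary together was checked on deviations from group means: the correlation was over 0.1 in 14 of 24 pairs, from -0.03 to 0.61, and 15 libraries correlated best with their own partner. The deposited TE values pair these columns, so TE was also fitted with a block that treats each pair as 1 culture. The main TE fit did not use this pairing, and results blocked by culture stand beside it. The pipeline was tested on simulated data with 200 changed genes: calls recovered 56.7% to 94.0% of genes changed 1.5-fold and 95.5% to 100.0% of those changed 4-fold, and 4.68% to 9.20% of calls were false.

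Alternatives were DESeq2 1.42.0 (its size factors within edgeR, and its Wald test), limma voom with quality weights, other filters, a fold of at least 1.5, counts of both assays thinned to the total of the smallest library of the experiment, a block by replicate or by culture, only the 2 groups compared, the deposited TE values, each library left out in turn, and an estimated correlation for lists. Counts were first thinned by drawing a fixed total per library, and binomial thinning replaced it after those values were seen. Alternatives chosen after seeing the data were library totals with no normalization factors, deposited TE values less the library median, leaving out Starved 1 and Starved 5, and leaving out Empty_vector C and C27F2.4 A, the libraries farthest from their group on the first principal component of mRNA-seq. Without them, on that component, Starved lies closer to Fed, and C27F2.4 lies closer to Empty_vector and farther from E02H1.1. Changes of counts and calls without these libraries therefore follow in part from how they were chosen.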

Results

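The series held 24 mRNA-seq libraries of polyadenylated RNA and 24 Ribo-seq libraries, made from ribosome-protected footprints, of the nematode Caenorhabditis elegans. A first experiment compared Fed with Starved worms (6 libraries per group and assay), and a second compared worms on RNAi against E02H1.1 or against C27F2.4 with worms on the Empty_vector control (4 libraries per group and assay). In RNAi, worms take up double-stranded RNA that lowers the matching transcript. The series title concerns hormesis passed between generations and inherited methylation of 18S ribosomal RNA. E02H1.1 is the worm homologue of the dimethyladenosine transferase DIMT1 and C27F2.4 that of the guanine methyltransferase BUD23, both acting on 18S ribosomal RNA. Totals ran from 19.2 to 22.8 M counts per mRNA-seq library and from 3.91 to 11.7 M per Ribo-seq library. Ribo-seq depth differed between groups, with means of 5.97 M in Fed, 4.91 M in Starved, 7.52 M in Empty_vector, 5.41 M in E02H1.1 and 9.37 M in C27F2.4. The labels do not say that replicates were separate cultures, so p-values measure the spread between these samples. The source label reads young adult, while 38 transcripts of adult yolk, adult cuticle and sperm summed to 3.02 to 5.99 CPM (counts scaled to library size) per mRNA-seq library. In the same libraries 7 transcripts listed as embryonic sheath and cuticle markers, picked after their abundances were seen, summed to 9102 to 11050 CPM. Markers that tell embryos from larvae were not examined. Values are mean CPM ± SD or log2 fold changes ± SE, with n = 6 per group for Starved and Fed and n = 4 per group for the knockdowns. Translational efficiency (TE) is the change in footprints less the change in mRNA.

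Each knocked-down transcript was reduced in its own libraries. E02H1.1 (WBGene00008455) stood at 19.1 ± 1.63 CPM in the mRNA-seq of its RNAi libraries against 67.6 ± 5.97 CPM in Empty_vector and fell by 1.83 on the log2 scale (SE 0.07, edgeR adjusted p = 1.18e-16). Its footprints stood at 11.23 ± 2.68 against 45.3 ± 2.99 CPM (-1.99 ± 0.11, adjusted p = 4.43e-11). C27F2.4 (WBGene00016166) stood at 31.6 ± 2.24 against 61.9 ± 4.68 CPM in mRNA-seq (-0.98 ± 0.07, adjusted p = 1.32e-10) and at 20.8 ± 1.75 against 61.6 ± 1.07 CPM in Ribo-seq (-1.59 ± 0.08, adjusted p = 1.54e-12). In every library of its own RNAi group, in both assays, the targeted gene lay below every Empty_vector library. TE of C27F2.4 itself fell in its own knockdown (-0.61 ± 0.10, adjusted p = 0.00367), and TE of E02H1.1 in the E02H1.1 libraries stood at -0.17 ± 0.14 (adjusted p = 0.492) and, without E02H1.1 D, at -0.37 (adjusted p = 0.127). E02H1.1 did not pass the test in the C27F2.4 libraries (mRNA -0.13 ± 0.07, footprints -0.06 ± 0.08). C27F2.4 was at -0.18 ± 0.07 in the mRNA-seq of the E02H1.1 libraries (adjusted p = 0.0317), a call that was lost on leaving out any 1 of 6 libraries. Its footprints there did not pass the test (0.00 ± 0.07). Neither gene passed the test in Starved against Fed: E02H1.1 was at -0.07 ± 0.05 in mRNA and -0.01 ± 0.08 in footprints, and C27F2.4 at 0.04 ± 0.05 and -0.08 ± 0.06.

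**Figure D1:**
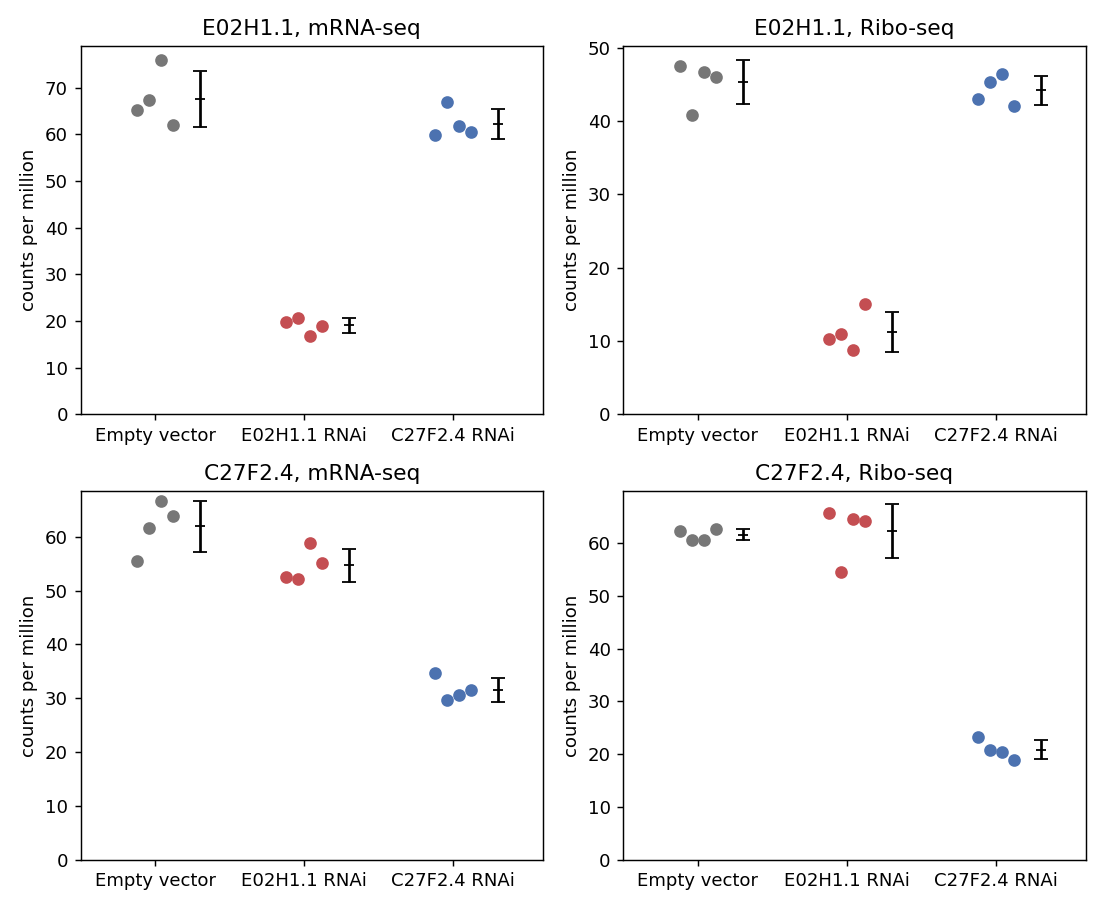
CPM of E02H1.1 and C27F2.4 in each knockdown-experiment library, by assay and group, with points for libraries and bars for the group mean and SD (n = 4). The 4 E02H1.1 libraries average 19.1 CPM of E02H1.1 mRNA against 67.6 in Empty_vector, and the 4 C27F2.4 libraries 31.6 CPM of C27F2.4 mRNA against 61.9.

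The comparison of Starved with Fed asks what the nutritional history changed in the collected worms. Heat shock genes rose in mRNA: hsp-70, an inducible chaperone, stood at 179 ± 33.2 CPM in Starved against 43 ± 5.71 in Fed (2.09 ± 0.13, edgeR adjusted p = 1.88e-06, n = 6), and hsp-16.2, a small heat shock protein, at 595 ± 122 against 159 ± 25.2 CPM (1.93 ± 0.15). Of the 20 cytosolic heat shock genes tested, 17 rose (17 adjusted over the list alone), with a median of 0.95 (camera adjusted p = 9.94e-17). The near-identical pair F44E5.4 and F44E5.5 (1.91 and 2) and the hsp-16 pairs can share reads, so the split between copies is uncertain. Among single genes, the solute carrier slc-17.5 rose by 1.45 ± 0.12, the poly(A) polymerase tent-5 by 1.39 ± 0.14 and the antimicrobial peptide gene cnc-4 by 1.36 ± 0.09. The kinase gene wee-1.1 (-0.67 ± 0.08), Y106G6H.9 (-0.78 ± 0.09) and T27E9.6 (-0.70 ± 0.11) fell. Over the transcriptome, 2915 of 13293 genes passed an adjusted p of 0.05, 1564 higher and 1351 lower, and 290 of them changed by at least 1.5-fold (236 up and 54 down). Scaled by library totals alone, 1216 were higher and 2012 lower, and with mRNA-seq thinned to 3.91 M counts, the total of the smallest Ribo-seq library, 1752 passed.

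Of 5 lists on metabolism and autophagy that were higher in Starved mRNA, lipid metabolism and oxidative phosphorylation held with an estimated correlation; counts in brackets are those adjusted over the list alone. In the lipid metabolism and fasting list, 22 of 54 rose and 1 fell (24 and 3), among them the stearoyl-CoA desaturase fat-6 (35.4 ± 4.62 against 18.1 ± 2.61 CPM, 1 ± 0.09) and acdh-2, an acyl-CoA dehydrogenase gene (0.67 ± 0.06), while ech-1.1 fell (-0.32 ± 0.08). In nuclear-encoded oxidative phosphorylation, 21 of 45 rose and 1 fell (25 and 2) (median 0.10), with the cytochrome c oxidase subunit cox-6C at 0.42 ± 0.07. In glycolysis, gluconeogenesis and the tricarboxylic acid cycle, 23 of 48 rose (24), including icl-1 of the glyoxylate cycle (0.49 ± 0.05) and pck-1 of gluconeogenesis (0.45 ± 0.07). Among propionate shunt and one-carbon genes 12 of 29 rose and 3 fell (13 and 4). Among autophagy and lysosome genes 18 of 60 rose and 1 fell (19 and 1), with the aspartic protease asp-1 at 0.39 ± 0.09. The calls for heat shock, oxidative phosphorylation and lipid metabolism held with an estimated correlation between members (adjusted p = 0.0338 for each). Those for glycolysis (camera adjusted p = 7.88e-12), propionate (0.00776) and autophagy (9.32e-04) did not, with adjusted p = 0.110, 0.271 and 0.206 with an estimated correlation.

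Cytosolic ribosomal protein genes rose almost as a whole in Starved mRNA; counts in brackets are those adjusted over the list alone. Of them, 71 of 73 rose (71), with a median of 0.27 (camera adjusted p = 3.96e-41, but adjusted p = 0.147 with an estimated correlation). The ribosomal gene rpl-29 stood at 255 ± 46.8 against 129 ± 35.8 CPM (1.02 ± 0.19). Among mitochondrial ribosomal protein genes 13 of 65 rose and 1 fell (13 and 1). For innate immunity 16 of 39 rose (17). For oxidative stress and detoxification 11 of 43 rose and 2 fell (12 and 2), among them the cytochrome P450 gene cyp-35C1 (0.55 ± 0.08). For the endoplasmic reticulum and mitochondrial unfolded protein response 7 of 26 rose and 1 fell (8 and 1), including the mitochondrial chaperone hsp-6 (0.37 ± 0.04). Among muscle genes 23 of 38 rose and 1 fell (29 and 1), with troponin T tnt-2 at 0.42 ± 0.10. Among cuticle collagens 21 of 101 rose and 2 fell (21 and 2), with col-97 at 0.50 ± 0.11. Among intestine markers 7 of 25 rose and 1 fell (8 and 2) and among neuron markers 7 of 40 rose (7). All of these lists passed camera with the preset correlation, but other splits of the same libraries put a median of 10 lists past the threshold. With an estimated correlation the adjusted p was 0.166 for mitochondrial ribosomal proteins, 0.101 for immunity, 0.206 for detoxification and 0.269 for the unfolded protein response. It was 0.337 for muscle, 0.410 for collagens, 0.410 for intestine and 0.638 for neurons. Without Starved 1 and Starved 5, left out after seeing the data, the calls for intestine (adjusted p = 0.134) and neurons (0.949) ended. Scaled by library totals, that for the unfolded protein response did (0.0569).

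Germline genes were lower in Starved mRNA; counts in brackets are those adjusted over the list alone. For germline nuclei and meiosis 14 of 40 fell (15), including the replication licensing factor mcm-3 at -0.38 ± 0.04 (list median -0.13, camera adjusted p = 6.57e-08, and adjusted p = 0.320 with an estimated correlation). In the heritable small RNA and chromatin list, 3 of 55 rose and 13 fell (3 and 13) (camera adjusted p = 9.59e-04, and adjusted p = 0.410 with an estimated correlation). The helicase gene drh-1 was at -0.32 ± 0.07 and the histone methyltransferase gene set-25 at -0.28 ± 0.05. That call also ended without Starved 1 and Starved 5 (adjusted p = 0.135). Oocyte and eggshell genes did not pass as a list (adjusted p = 0.0611), although 1 of 34 rose and 4 fell (1 and 4), with the germ granule gene meg-1 at -0.43 ± 0.06. The 7 lists that come next did not pass either. Among translation factors 4 of 47 rose and 8 fell (4 and 10) (adjusted p = 0.389), among aminoacyl-tRNA synthetases 6 of 30 rose (6) (0.126). In ribosome biogenesis and rRNA modification 4 of 41 rose and 7 fell (4 and 10) (0.0731), and in insulin signalling and DAF-16 targets 7 of 30 rose and 4 fell (8 and 5) (0.111). For the proteasome, 3 of 33 rose and 2 fell (2 and 1) (0.974). For replication-dependent histones 2 of 34 rose and 5 fell (2 and 5) (0.246), and for sperm 1 of 10 fell (1) (0.946). The proteasome and sperm lists had medians (0.01 and 0.06) and means above 0 and a test pointing down. Of 6 vitellogenins 1 was tested and did not pass over all genes (1 adjusted over the list alone), and no gene of the mitochondrially encoded list could be matched by name. As many lists as the 17 past the threshold were reached in 14 of 100 splits of the same 12 libraries, the real one included.

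Footprints of fasting genes rose in Starved as a list, and single genes of other functions rose or fell. In Ribo-seq, hsp-70 stood at 626 ± 95.2 CPM in Starved against 108 ± 34.8 in Fed (2.54 ± 0.21, edgeR adjusted p = 6.46e-06, n = 6) and hsp-16.2 at 2.4 ± 0.17. The flavin monooxygenase fmo-2 (1.4 ± 0.18), fat-6 (1.1 ± 0.10), tent-5 (1.76 ± 0.16), slc-17.5 (1.70 ± 0.14) and the lipid-related transcription factor mxl-3 (0.61 ± 0.07) also rose. Footprints fell on the Argonaute genes wago-4 (-0.73 ± 0.13) and wago-1 (-0.49 ± 0.06), the germ granule genes glh-4 (-0.72 ± 0.11) and pgl-1 (-0.54 ± 0.06), the poly(A) polymerase gene pap-3 (-0.72 ± 0.08) and dsb-1, which acts in meiotic recombination (-0.66 ± 0.10). The initiation factor eif-2A (-0.51 ± 0.06), the leucyl-tRNA synthetase lars-1 (-0.35 ± 0.05), nucleolin nucl-1 (-0.34 ± 0.04), the ribosome biogenesis factor lpd-7 (-0.36 ± 0.05) and the proteasome subunit rpn-2 (-0.43 ± 0.05) fell too. In all, 3033 of 10589 genes passed, 1475 higher and 1558 lower, and 151 changed by at least 1.5-fold (109 up and 42 down).

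By list, with counts adjusted over the list alone in brackets, 21 of 48 rose and 1 fell (22 and 1) among lipid metabolism and fasting genes in footprints, and this call alone of 15 held with an estimated correlation (adjusted p = 0.00988). Among heat shock genes 9 of 13 rose (10) (adjusted p = 0.0784 with an estimated correlation). Germline nuclei and meiosis genes were lower, as 1 of 38 rose and 23 fell (1 and 24), with a median of -0.27 (camera adjusted p = 5.03e-10). In the small RNA and chromatin list 27 of 55 fell (28), and in that of oocyte and eggshell 12 of 24 fell (13), with mex-1 at -0.39 ± 0.06. In ribosome biogenesis 1 of 41 rose and 21 fell (1 and 23). With an estimated correlation the adjusted p was 0.144, 0.246, 0.232 and 0.0652 for these 4 lists in turn. Among proteasome subunits 2 of 32 rose and 17 fell (2 and 21), and among translation factors 3 of 46 rose and 19 fell (3 and 19) (adjusted p = 0.398 and 0.288 with an estimated correlation). Among cytosolic ribosomal proteins 16 of 73 rose and 1 fell (16 and 1), with a median of 0.10 against 0.27 in mRNA (camera adjusted p = 3.78e-04, adjusted p = 0.675 with an estimated correlation), and rps-27 (0.45 ± 0.07) and rps-29 (0.37 ± 0.06) rose. Of the 15 lists past the threshold of camera, 8 pointed up and 7 down. For muscle 15 of 38 rose and 1 fell (16 and 1) and for oxidative stress and detoxification 13 of 36 rose and 1 fell (13 and 1), with adjusted p = 0.484 and 0.0551 with an estimated correlation. Among glycolysis, gluconeogenesis and tricarboxylic acid cycle 16 of 48 rose and 5 fell (16 and 5) and among aminoacyl-tRNA synthetases 9 of 30 fell (10), with adjusted p = 0.520 and 0.191 with an estimated correlation. In innate immunity 7 of 28 rose and 1 fell (7 and 1) and in mitochondrial ribosomal proteins 9 of 65 rose (5), with adjusted p = 0.483 and 0.288 with an estimated correlation. Without Starved 1 and Starved 5 the calls for innate immunity and mitochondrial ribosomal proteins ended (adjusted p = 0.0978 and 0.0525), and the latter also with DESeq2 (0.0768), no filter (0.0513) and thinned counts (0.0793). Of the 2706 genes called in mRNA and tested in both assays, 1248 were also called in the same direction in footprints and 47 in the opposite one. The fold changes of 10572 genes correlated at r = 0.56 across genes, which are not independent replicates.

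TE fell in Starved among aminoacyl-tRNA synthetases and for single genes of other functions. It fell for elongation factor eef-2 (-0.58 ± 0.06, edgeR adjusted p = 3.54e-09, n = 6), and for eef-1A.1 (-0.63 ± 0.13), which can share reads with a near-identical copy. It also fell for the ribosome biogenesis factor lpd-7 (-0.59 ± 0.06), for glyceraldehyde-3-phosphate dehydrogenase gpd-1 (-0.65 ± 0.10), again with near-identical copies, for the muscle myosin unc-54 (-0.58 ± 0.10) and for the aspartic protease asp-6 (-1.08 ± 0.24). TE of the germ granule genes glh-4 (-0.67 ± 0.14) and pgl-1 (-0.54 ± 0.12) and the saposin-like gene spp-14 (-0.72 ± 0.16) also fell. The ESCRT gene vps-24 rose (0.49 ± 0.08). ebp-1 (0.50 ± 0.09) and R12E2.15 (-1.21 ± 0.27) can share reads with near-identical copies and are uncertain, and R12E2.15 did not pass without Starved 1 and Starved 5. With counts adjusted over the list alone in brackets, 6 of 30 fell (11) among aminoacyl-tRNA synthetases, such as lars-1 (-0.49 ± 0.06) and iars-1 (-0.38 ± 0.05). This list's call held with an estimated correlation (adjusted p = 0.0494). Among cytosolic ribosomal proteins 9 of 73 fell (16), with a median of -0.18 (camera adjusted p = 4.10e-12, adjusted p = 0.471 with an estimated correlation). In oxidative phosphorylation 8 of 45 fell (2 up and 22 down) and among proteasome subunits 8 of 32 fell (15), with adjusted p = 0.405 for both with an estimated correlation. Of the 14 lists past the threshold of camera, 1 pointed up and 13 down. For ribosome biogenesis and rRNA modification 1 of 41 rose and 9 fell (2 and 12) and for heritable small RNA and chromatin pathways 8 of 55 fell (12), with adjusted p = 0.405 and 0.490 with an estimated correlation. Among glycolysis, gluconeogenesis and tricarboxylic acid cycle 1 of 48 rose and 5 fell (3 and 9) and among translation factors 1 of 46 rose and 8 fell (4 and 14), with adjusted p = 0.490 and 0.405 with an estimated correlation. In germline nuclei and meiosis 1 of 38 rose and 5 fell (1 and 7) and in oocyte and eggshell none of 24 passed (none) though the list pointed down, with adjusted p = 0.490 and 0.490 with an estimated correlation. For propionate shunt and one-carbon metabolism 4 of 28 fell (1 up and 6 down) and for replication-dependent histones 3 of 30 rose (4), with adjusted p = 0.405 and 0.490 with an estimated correlation. Among innate immunity 1 of 28 fell (1) and among endoplasmic reticulum and mitochondrial unfolded protein response 2 of 26 fell (1 up and 6 down), with adjusted p = 0.410 and 0.405 with an estimated correlation. Calls for replication-dependent histones, innate immunity and endoplasmic reticulum and mitochondrial unfolded protein response ended with a filter of 5 CPM (adjusted p = 0.292, 0.0900 and 0.0571). For histones it also ended on deposited values less the library median (0.187) and for the unfolded protein response there (0.0877), on the values as deposited (0.0984), scaled by library totals (0.0955) and with replicates (0.0574) or cultures (0.0565) as a block. Of 10572 genes 665 passed, 269 higher and 396 lower (539 and 278 scaled by library totals), 38 of them by at least 1.5-fold (7 up and 31 down). With the same-named mRNA-seq and Ribo-seq libraries as a block by culture, 1145 passed. Leaving out Fed 4, Fed 5 or Starved 5 lowered the count to 430, 425 or 422, and 62 passed on the deposited unscaled TE values, 61 of them lower. There vps-24, lars-1, iars-1 and ebp-1 did not pass, and spp-14 did not with DESeq2.

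**Figure D2:**
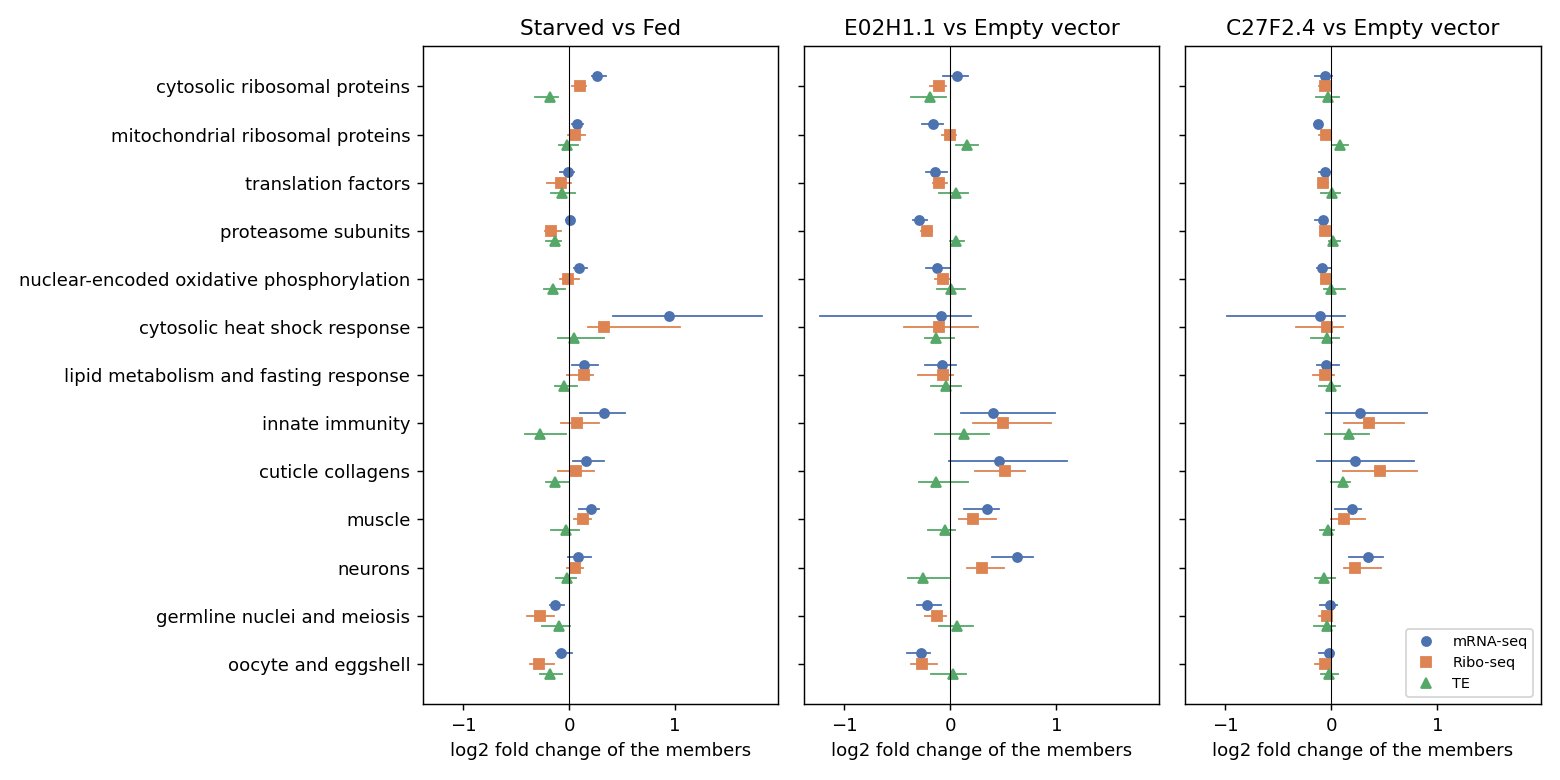
Median log2 fold change of the members tested in 13 of the gene lists, with the quartiles as lines, for mRNA-seq, Ribo-seq and TE in Starved against Fed and in each knockdown against Empty vector. In Starved, cytosolic ribosomal proteins lie at 0.27 in mRNA and -0.18 in TE, and in E02H1.1 knockdown neurons lie at 0.63 in mRNA.

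Knockdown of E02H1.1 asks what lowering this 18S ribosomal RNA methyltransferase homologue changed. F08G2.5 rose from 0.667 ± 0.234 to 35 ± 1.19 CPM in mRNA (5.70 ± 0.17, edgeR adjusted p = 4.91e-20, n = 4) and stood at 4.04 ± 0.628 CPM in the C27F2.4 libraries. F08G2.5 is not among the Ribo-seq genes, so its footprints and TE could not be examined. The tyrosinase gene tyr-2 (2.06 ± 0.16), the myo-inositol transporter gene hmit-1.1 (2.29 ± 0.17), the C-type lectin clec-67 (1.76 ± 0.18) and M01G12.9 (2.41 ± 0.10) also rose. The acyl-CoA dehydrogenase acdh-2 fell from 30.9 ± 6.16 to 5.97 ± 1.14 CPM (-2.38 ± 0.16), and hsp-16.2 (-1.74 ± 0.24), hsp-16.41 (-1.54 ± 0.22) and C09B8.4 (-1.44 ± 0.14) fell. Of 13637 genes 5393 passed, 2720 higher and 2673 lower, and 1391 changed by at least 1.5-fold, 1196 of these upward. With mRNA-seq thinned to 4.23 M counts, the total of the smallest Ribo-seq library of this experiment, 3333 passed.

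Many neuronal, muscle and cuticle genes rose and proteasome genes fell in E02H1.1 mRNA, but no list call held with an estimated correlation; counts in brackets are those adjusted over the list alone. Among neuronal genes 34 of 40 rose and 1 fell (34 and 2), with a median of 0.63, including unc-25, which makes GABA (0.95 ± 0.12), and egl-21, which processes neuropeptides (0.84 ± 0.09). Among muscle genes 27 of 38 rose (29), with pharyngeal myosin myo-1 at 1.03 ± 0.14 and tnt-2 at 1.08 ± 0.14. Among cuticle collagens 52 of 108 rose and 2 fell (54 and 3), with col-144 at 1.70 ± 0.11. For innate immunity 20 of 44 rose and 1 fell (21 and 1), with dod-19 at 1.49 ± 0.14. Proteasome subunits fell almost as a whole: 32 of 33 fell (32), with a median of -0.29, rpn-12 at -0.50 ± 0.07 and pas-5 at -0.44 ± 0.06. Among translation factors 4 of 47 rose and 28 fell (4 and 30), including iff-1, an eIF-5A gene (-0.50 ± 0.05). Among mitochondrial ribosomal proteins 1 of 65 rose and 28 fell (1 and 28), with mrpl-36 at -0.74 ± 0.16. Among oocyte and eggshell genes 2 of 34 rose and 14 fell (2 and 15), with cey-3 at -0.66 ± 0.13 and puf-5 at -0.66 ± 0.16. Camera adjusted p values of these 8 lists ran from 2.49e-14 to 3.72e-04. None of the 15 lists past the threshold held with an estimated correlation, where the adjusted p was 0.381 for neurons, 0.479 for muscle, 0.267 for collagens and 0.244 for immunity. It was 0.466 for the proteasome, 0.501 for translation factors, 0.0533 for mitochondrial ribosomal proteins and 0.529 for oocytes. Of the 15 lists past the threshold of camera, 5 pointed up and 10 down. For germline nuclei and meiosis 1 of 40 rose and 19 fell (2 and 19) and for nuclear-encoded oxidative phosphorylation 5 of 45 rose and 21 fell (7 and 24), with adjusted p = 0.529 and 0.501 with an estimated correlation. Among heritable small RNA and chromatin pathways 4 of 55 rose and 17 fell (4 and 18) and among ribosome biogenesis and rRNA modification 1 of 41 rose and 13 fell (1 and 12), with adjusted p = 0.529 and 0.529 with an estimated correlation. In endoplasmic reticulum and mitochondrial unfolded protein response 2 of 26 rose and 12 fell (3 and 12) and in aminoacyl-tRNA synthetases 1 of 30 rose and 10 fell (0 up and 10 down), with adjusted p = 0.501 and 0.529 with an estimated correlation. Calls for nuclear-encoded oxidative phosphorylation, heritable small RNA and chromatin pathways, ribosome biogenesis and rRNA modification, endoplasmic reticulum and mitochondrial unfolded protein response and aminoacyl-tRNA synthetases ended with a filter of 5 CPM (adjusted p = 0.0599, 0.0538, 0.0974, 0.0974 and 0.140), and that for the synthetases with thinned counts (0.0608). In the cytosolic ribosomal protein list 25 of 73 rose and 7 fell (25 and 7), with rpl-4 at 0.33 ± 0.05 and ubl-1 at -0.32 ± 0.05. Its median was 0.06, its mean -0.01 and its test up (adjusted p = 0.0181, and adjusted p = 0.722 with an estimated correlation). The call ended without Empty_vector C and C27F2.4 A (adjusted p = 0.157).

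In E02H1.1 footprints the ribosomal proteins rps-12 and rps-13 fell, from 125 ± 5.85 to 50.5 ± 16.40 CPM (-1.31 ± 0.19, edgeR adjusted p = 0.00115, n = 4) and from 322 ± 4.93 to 186 ± 23.5 CPM (-0.80 ± 0.07). Footprints also fell on eif-2A (-0.76 ± 0.07), acdh-2 (-2.52 ± 0.31), ech-1.1, an enzyme gene of fatty acid oxidation (-0.98 ± 0.13), hsp-16.2 (-1.97 ± 0.26), the oocyte gene cey-2 (-0.79 ± 0.12) and wago-1 (-0.49 ± 0.07). They rose on hmit-1.1 (2.51 ± 0.18), clec-67 (2.04 ± 0.18), the vesicular acetylcholine transporter unc-17 (0.82 ± 0.18), the neuropeptide gene flp-11 (0.73 ± 0.18) and the collagen col-167 (1.04 ± 0.18). With counts adjusted over the list alone in brackets, 21 of 32 fell (30) among proteasome subunits, 19 of 73 fell (21) among cytosolic ribosomal proteins and 4 of 48 rose and 15 fell (4 and 16) among lipid metabolism and fasting genes. For collagens 25 of 50 rose (32), and for immunity 20 of 31 rose (23 up and 1 down). For neurons 15 of 36 rose (16 up and 1 down), and for muscle 15 of 38 rose (19). All 7 lists passed camera, and the lipid call, alone of 15, held with an estimated correlation (adjusted p = 0.0452). The others had adjusted p = 0.371 for the proteasome, 0.507 for ribosomal proteins, 0.305 for collagens, 0.275 for immunity, 0.399 for neurons and 0.399 for muscle with an estimated correlation. Of the 15 lists past the threshold of camera, 4 pointed up and 11 down. For heritable small RNA and chromatin pathways 16 of 55 fell (1 up and 19 down) and for oocyte and eggshell 10 of 25 fell (10), with adjusted p = 0.371 and 0.371 with an estimated correlation. Among translation factors 1 of 46 rose and 10 fell (1 and 13) and among aminoacyl-tRNA synthetases 10 of 30 fell (11), with adjusted p = 0.305 and 0.298 with an estimated correlation. In nuclear-encoded oxidative phosphorylation 10 of 45 fell (11) and in germline nuclei and meiosis 7 of 38 fell (9), with adjusted p = 0.371 and 0.503 with an estimated correlation. For endoplasmic reticulum and mitochondrial unfolded protein response 1 of 26 rose and 8 fell (1 and 9) and for ribosome biogenesis and rRNA modification 6 of 41 fell (6), with adjusted p = 0.305 and 0.399 with an estimated correlation. In total 2146 of 10736 genes passed, 1154 higher and 992 lower, and 568 changed by at least 1.5-fold (508 up and 60 down). Of 4784 genes called in mRNA and tested in both assays, 1172 were called the same way in footprints and 77 the opposite way.

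TE of cytosolic ribosomal proteins fell in the E02H1.1 knockdown: 30 of 73 fell (36 adjusted over the list alone), with a median of -0.19 (camera adjusted p = 4.42e-15, but adjusted p = 0.775 with an estimated correlation). Among them were rps-12 (-1.26 ± 0.18, edgeR adjusted p = 2.11e-04, n = 4) and rla-1 (-0.76 ± 0.11). Mitochondrial ribosomal proteins were higher as a list, with 9 of 65 past the test (15 higher and 1 lower adjusted over the list alone) and a median of 0.16. This call held with an estimated correlation (adjusted p = 0.0367), and mrps-7 rose by 0.43 ± 0.10. TE also fell for eif-2A (-0.85 ± 0.10), tent-5 (-0.94 ± 0.14), the intestinal proton pump subunit vha-6 (-1.05 ± 0.18), asp-6 (-1.1 ± 0.20), the G protein alpha subunit gsa-1 (-0.94 ± 0.14), the pyruvate dehydrogenase subunit dlat-1 (-0.37 ± 0.08) and C32F10.4 (-0.97 ± 0.13). It rose for emb-1, a subunit gene of the anaphase-promoting complex (1.25 ± 0.22). The neuronal list was lower in TE by camera (median -0.26 beside 0.63 in mRNA and 0.30 in footprints, adjusted p = 9.81e-04, but adjusted p = 0.775 with an estimated correlation), with 2 of 36 lower (2 adjusted over the list alone). For glycolysis, gluconeogenesis and tricarboxylic acid cycle 3 of 48 rose and 10 fell (4 and 12), with adjusted p = 0.775 with an estimated correlation. That call ended scaled by library totals (adjusted p = 0.0647), without Empty_vector C and C27F2.4 A (0.0536) and on the deposited TE values (0.0897). Of 10714 genes 1160 passed, 599 higher and 561 lower, 146 of them by at least 1.5-fold (88 up and 58 down), and 2227 passed with cultures as a block. The balance turned with the processing: 731 were higher and 514 lower scaled by library totals. On deposited values less the library median 591 were higher and 895 lower, and with the DESeq2 Wald test 517 and 803. Leaving out Empty_vector B, E02H1.1 B or E02H1.1 D lowered the count to 763, 594 or 723, and on the deposited unscaled TE values 759 passed, 12 higher and 747 lower, and mrps-7 did not.

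Knockdown of C27F2.4 asks the same of the BUD23 homologue. In mRNA tyr-2 rose from 6.78 ± 1.39 to 23.1 ± 4.08 CPM (1.75 ± 0.17, edgeR adjusted p = 1.38e-06, n = 4), as did K10H10.4 (2.1 ± 0.15), the collagens col-130 (1.51 ± 0.11) and col-168 (1.5 ± 0.17), the ABC transporter gene pgp-14 (1.46 ± 0.20) and dod-19 (1.21 ± 0.14). acdh-2 fell from 30.9 ± 6.16 to 9.50 ± 1.68 CPM (-1.71 ± 0.15), and the cytochrome P450 gene cyp-13B1 (-1.2 ± 0.07), hsp-16.2 (-1.5 ± 0.23) and hsp-16.41 (-1.25 ± 0.22) fell. With counts adjusted over the list alone in brackets, 9 of 65 fell (9) among mitochondrial ribosomal proteins (median -0.12). This list's call was the 1 of 12 that held with an estimated correlation (adjusted p = 0.0174). Among neuronal genes 21 of 40 rose (23), with unc-25 at 0.67 ± 0.12 and the synaptotagmin snt-1 at 0.65 ± 0.10. Among muscle genes 19 of 38 rose (22), with the pharyngeal myosins myo-1 (0.85 ± 0.14) and myo-2 (0.86 ± 0.12), although C27F2.4 A stood above the other 3 C27F2.4 libraries in both (118.5 against 92.2 to 94.3 CPM and 171 against 135 to 140 CPM). For collagens 35 of 108 rose and 6 fell (38 and 8), and for immunity 13 of 44 rose and 1 fell (17 and 1), for example the C-type lectin clec-63 (0.79 ± 0.08). For intestine 8 of 25 rose and 1 fell (9 and 1), with ifc-2 at 0.84 ± 0.09 and asp-5 at 0.79 ± 0.08. With an estimated correlation the adjusted p was 0.495 for neurons, 0.624 for muscle, 0.483 for collagens, 0.410 for immunity and 0.624 for intestine. The intestine call ended without Empty_vector C and C27F2.4 A (adjusted p = 0.0520). Of the 12 lists past the threshold of camera, 5 pointed up and 7 down. For cytosolic ribosomal proteins 7 of 73 fell (6) and for nuclear-encoded oxidative phosphorylation 7 of 45 fell (1 up and 10 down), with adjusted p = 0.631 and 0.624 with an estimated correlation. Among translation factors 1 of 47 rose and 6 fell (1 and 7) and among proteasome subunits 1 of 33 fell (1), with adjusted p = 0.624 and 0.631 with an estimated correlation. In ribosome biogenesis and rRNA modification 3 of 41 fell (3) and in aminoacyl-tRNA synthetases none of 30 passed (none) though the list pointed down, with adjusted p = 0.631 and 0.624 with an estimated correlation. Without Empty_vector C and C27F2.4 A the list calls for translation factors, proteasome subunits, ribosome biogenesis and rRNA modification and aminoacyl-tRNA synthetases ended (adjusted p = 0.293, 0.828, 0.687 and 0.3). For ribosome biogenesis it also ended with a filter of 5 CPM (0.103) or only the 2 groups compared (0.0918), and for the synthetases under 6 other alternatives, with DESeq2 among them (0.0581). In all 1864 of 13637 genes passed, 1106 higher and 758 lower, 544 of them by at least 1.5-fold (455 up and 89 down). Without C27F2.4 B 1189 passed, and with mRNA-seq thinned to 4.23 M counts 977.

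C27F2.4 footprints rose on C06E8.5 (1.92 ± 0.23, edgeR adjusted p = 1.81e-05, n = 4), pqn-94 (1.90 ± 0.24), tyr-2 (1.67 ± 0.18), the collagens col-144 (1.33 ± 0.23) and col-167 (1.15 ± 0.17), dod-19 (1.02 ± 0.13), the synaptic vesicle gene rab-3 (0.40 ± 0.09) and xbp-1, a transcription factor of the unfolded protein response (0.30 ± 0.05). They fell on acdh-2 (-1.24 ± 0.23), ech-1.1 (-0.77 ± 0.12), eif-2A (-0.40 ± 0.07) and hsp-16.2 (-1.39 ± 0.24). Among lipid metabolism and fasting genes 8 of 48 fell (1 up and 12 down), where brackets hold counts adjusted over the list alone. This call alone of 16 held with an estimated correlation (adjusted p = 0.0437). For immunity 14 of 31 rose (16) and for collagens 21 of 50 rose (28 up and 2 down) (adjusted p = 0.140 and 0.225 with an estimated correlation). For neurons 3 of 36 rose (9) and for muscle 7 of 38 rose (9) (adjusted p = 0.418 and 0.647 with an estimated correlation). Both calls ended without Empty_vector C and C27F2.4 A (adjusted p = 0.115 and 0.603). Of the 16 lists past the threshold of camera, 5 pointed up and 11 down. For cytosolic ribosomal proteins 8 of 73 fell (11) and for aminoacyl-tRNA synthetases 3 of 30 fell (3), with adjusted p = 0.655 and 0.140 with an estimated correlation. Among translation factors 2 of 46 fell (2) and among ribosome biogenesis and rRNA modification 1 of 41 fell (1), with adjusted p = 0.228 and 0.296 with an estimated correlation. In endoplasmic reticulum and mitochondrial unfolded protein response 1 of 26 rose and 4 fell (1 and 5) and in proteasome subunits 1 of 32 fell (0 up and 0 down), with adjusted p = 0.168 and 0.655 with an estimated correlation. For heritable small RNA and chromatin pathways 2 of 55 fell (0 up and 0 down) and for nuclear-encoded oxidative phosphorylation none of 45 passed (none) though the list pointed down, with adjusted p = 0.539 and 0.418 with an estimated correlation. Among mitochondrial ribosomal proteins none of 65 passed (none) though the list pointed down and among germline nuclei and meiosis none of 38 passed (none) though the list pointed down, with adjusted p = 0.12 and 0.655 with an estimated correlation. In oxidative stress and detoxification 6 of 37 rose (7 up and 1 down), with adjusted p = 0.474 with an estimated correlation. Without Empty_vector C and C27F2.4 A the calls for proteasome subunits, heritable small RNA and chromatin pathways, germline nuclei and meiosis and oxidative stress and detoxification ended (adjusted p = 0.332, 0.646, 0.168 and 0.252). Those for germline nuclei and meiosis and oxidative stress and detoxification also ended with a filter of 5 CPM (adjusted p = 0.0659 for both) and the former with thinned counts (0.0615). In total 760 of 10736 genes passed, 533 higher and 227 lower, 353 of them by at least 1.5-fold (330 up and 23 down). The balance rested on the libraries and the scaling: 603 were higher and 154 lower scaled by library totals, and 317 higher and 358 lower without Empty_vector C and C27F2.4 A. Without Empty_vector A or Empty_vector C, 490 or 482 passed.

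TE changed for 94 of 10714 genes in the C27F2.4 knockdown, 39 higher and 55 lower (52 and 50 scaled by library totals). It fell for C27F2.4 itself, for eif-2A (-0.60 ± 0.10, adjusted p = 0.00367) and for the uridylyltransferase gene pup-2 (-0.45 ± 0.08). These 3 calls were lost on the deposited unscaled TE values, where 1184 genes passed and 1183 of them were higher. With cultures as a block 662 passed, and 236 did without Empty_vector C and C27F2.4 A. Leaving out C27F2.4 A raised the count to 227, while leaving out C27F2.4 B, C27F2.4 C, Empty_vector A, Empty_vector B or Empty_vector D lowered it to 15, 9, 20, 23 or 19, so single TE calls of this knockdown rest on few libraries. Mitochondrial ribosomal proteins had a TE median of 0.08 (camera adjusted p = 0.0281, but adjusted p = 0.489 with an estimated correlation), and no member passed over all genes or adjusted over the list alone. This call ended without Empty_vector C and C27F2.4 A (adjusted p = 0.12). Of the 3 lists past the threshold of camera, 1 pointed up and 2 down. For glycolysis, gluconeogenesis and tricarboxylic acid cycle 1 of 48 fell (1) and for heritable small RNA and chromatin pathways 1 of 55 fell (2), with adjusted p = 0.883 and 0.883 with an estimated correlation. The small RNA call ended without Empty_vector C and C27F2.4 A (adjusted p = 0.0931) and with a filter of 5 CPM (0.0550), and on the deposited TE values both did (0.140 for glycolysis and 0.147 for small RNA). Leaving out Empty_vector C alone left no list past the threshold, and leaving out C27F2.4 C alone left 1.

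**Figure D3:**
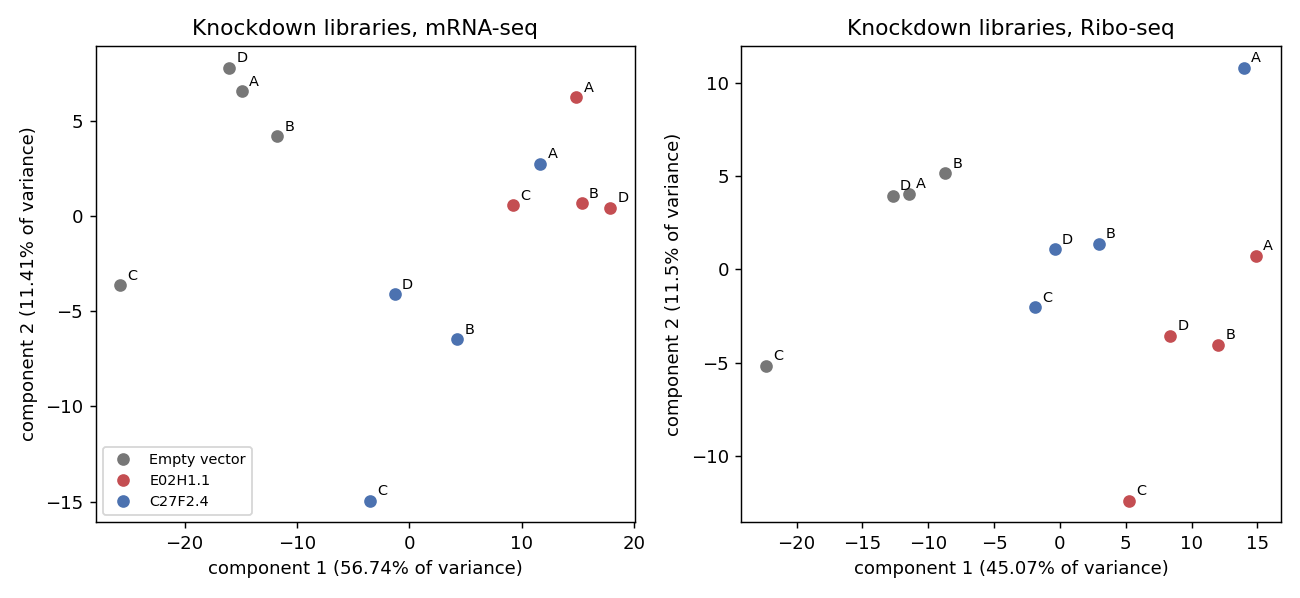
First 2 principal components of log2 CPM for the knockdown libraries, in mRNA-seq and Ribo-seq, with 1 point per library coloured by group. In mRNA-seq component 1 (56.7% of variance) runs from Empty_vector C at -25.7 to E02H1.1 D at 17.9, and the C27F2.4 libraries lie from -3.51 to 11.7.

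Compared directly, the E02H1.1 and C27F2.4 knockdowns differed by 445 genes in mRNA, 222 higher and 223 lower in E02H1.1 (186 and 292 scaled by library totals), and by 134 in footprints, 66 higher and 68 lower. With counts adjusted over the list alone in brackets, proteasome subunits were lower in E02H1.1 mRNA, as 15 of 33 fell (29) (median -0.20, limma camera adjusted p = 5.21e-20, and adjusted p = 0.326 with an estimated correlation). Germline genes were lower too, as 10 of 40 fell (1 up and 16 down) (adjusted p = 0.406 with an estimated correlation). Among cytosolic ribosomal proteins 18 of 73 rose (39 up and 1 down) (adjusted p = 0.406 with an estimated correlation). In footprints of the same list 5 of 73 fell (8) and in TE none passed (0 up and 24 down), with medians of -0.05 and -0.21 (camera adjusted p = 3.72e-05 and 8.34e-30, but adjusted p = 0.676 and 0.545 with an estimated correlation). None of the 13, 10 and 7 lists past the threshold of camera in mRNA, footprints and TE held with an estimated correlation. In TE 5 genes differed, named after their values were seen. C27F2.4 was higher in the E02H1.1 libraries (0.79 ± 0.10, edgeR adjusted p = 1.20e-04). It is the transcript targeted in the group compared with, and its TE fell there against Empty_vector, as given above. C32F10.4 (-0.75 ± 0.12), T01G1.4 (-0.43 ± 0.08), skr-21 (-0.36 ± 0.07) and ztf-7 (-0.34 ± 0.07) were lower. In TE 260 differed with cultures as a block. Leaving out 1 library moved these counts by more than 1.5 times, and without both Empty_vector C and C27F2.4 A 2649 genes differed in mRNA, 929 in footprints and 54 in TE. Both were picked after seeing component 1 of mRNA-seq, where C27F2.4 A (11.7) lay among the E02H1.1 libraries. Leaving it out therefore favours a larger difference by the choice alone. For mRNA, 1713 passed without C27F2.4 A and 1085 without Empty_vector C. The mRNA count fell by 322 without C27F2.4 B, to 152 and 135 without C27F2.4 C or D, and to 155, 84 and 151 without E02H1.1 A, B or D. For footprints, 413 passed without C27F2.4 A, 273 without Empty_vector C, 72 without C27F2.4 D, and 83 and 69 without E02H1.1 A or B. For TE, 20 passed without Empty_vector C, 2 without each of C27F2.4 A, C27F2.4 B, C27F2.4 D or Empty_vector B, and 1 without E02H1.1 B or C. Another split of these 8 libraries gave 644 genes in mRNA, more than the 445 of the real one.

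Genes called in both knockdowns moved almost entirely the same way. In mRNA 1034 genes were higher and 651 lower in both (220.6 and 148.6 from independent lists), and no gene called in both went opposite ways. tyr-2, K10H10.4 and col-168 were among the shared higher genes and acdh-2 and hsp-16.2 among the lower. In footprints 440 were higher and 183 lower in both (57.3 and 20.97 from independent lists), with 1 opposite, and in TE 33 and 51 (2.18 and 2.88), eif-2A among the latter. These comparisons share the 4 Empty_vector libraries. In 20 simulations of unchanged groups against shared controls the fold changes correlated at r = 0.50 in mRNA, 0.49 in footprints and 0.49 in TE, against 0.80, 0.82 and 0.68 observed. The simulations drew each gene independently and so lack variation that many genes of a library share. They cannot show how far such variation in the shared controls alone could move r or the covariance. The covariance was 0.133, 0.0650 and 0.0388, against 0.0188, 0.00984 and 0.0173 simulated, which leaves 0.114, 0.0552 and 0.0214. With 2 Empty_vector libraries for each knockdown, in 6 orientations, 428 to 1190 genes in mRNA, 84 to 237 in footprints and up to 9 in TE were shared (89.2 to 184 and 8.76 to 21.3 from independent lists in the first 2), with r of 0.46 to 0.53, 0.58 to 0.66 and 0.33 to 0.36 and a mean covariance of 0.1198, 0.0561 and 0.0247. The shared count fell to 1115 in mRNA without C27F2.4 B. In footprints it fell to 413 and 378 without Empty_vector A or C. In TE it rose to 197 without C27F2.4 A and fell to 14, 8, 19, 20 and 18 without C27F2.4 B, C27F2.4 C, Empty_vector A, Empty_vector B and Empty_vector D. With cultures as a block 529 TE genes were shared, and 210 in TE and 1095 in mRNA without both Empty_vector C and C27F2.4 A.

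**Figure D4:**
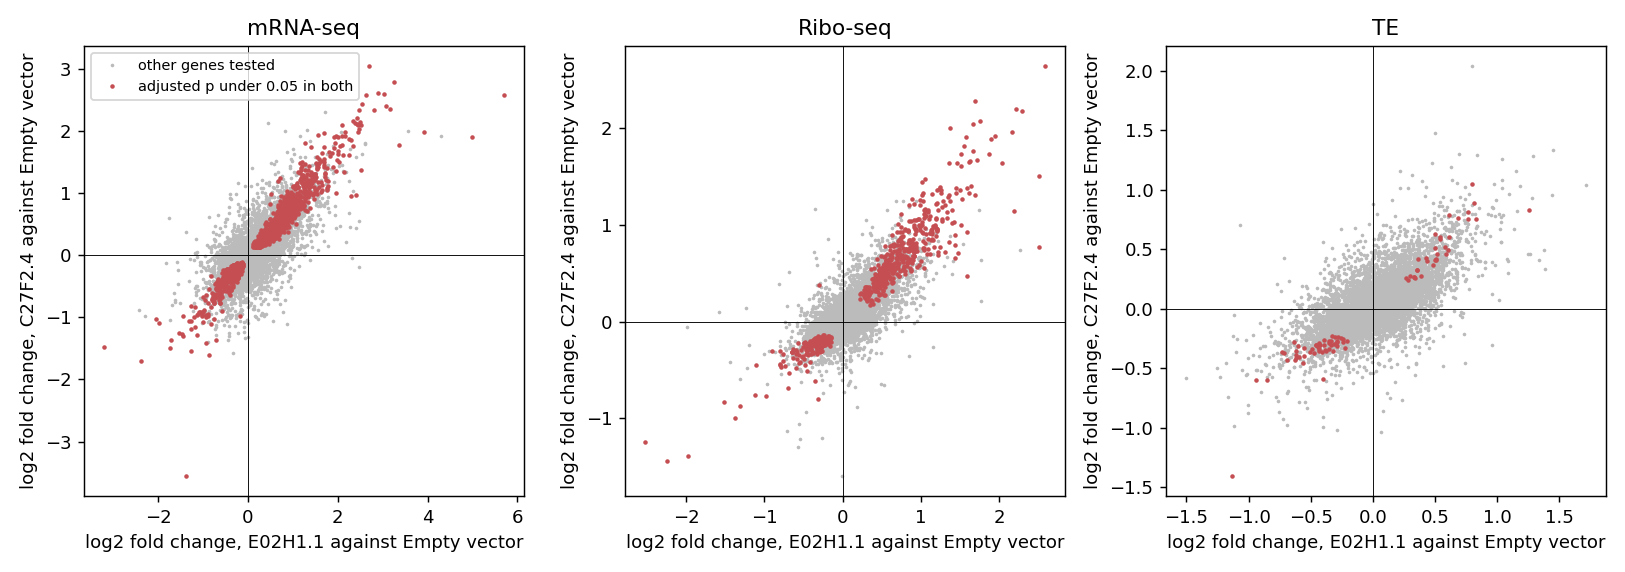
Log2 fold changes of each gene tested in E02H1.1 against Empty_vector (horizontal) and C27F2.4 against Empty_vector (vertical), in mRNA-seq, Ribo-seq and TE, with genes called in both knockdowns in red. The correlations across genes are 0.80, 0.82 and 0.68, where simulated unchanged groups sharing the controls give 0.50, 0.49 and 0.49. The simulation drew each gene independently, without variation that many genes of a library share.

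The last comparison asked whether genes that moved with starvation also moved with a knockdown; the experiments share no libraries. Some genes went opposite ways, as hsp-16.2 mRNA rose in Starved (1.93) and fell in E02H1.1 (-1.74) and C27F2.4 (-1.5), and acdh-2 did likewise (0.67, -2.38 and -1.71). The hsp-16 pairs can share reads. Heat shock genes as a list did not pass in mRNA of either knockdown. In E02H1.1 4 of 20 rose and 7 fell (camera adjusted p = 0.726), and in C27F2.4 4 rose and 6 fell (0.429). In TE, 84 genes were lower in both Starved and E02H1.1 (20.99 from independent lists), with 20 higher in both (15.2) and 33 opposite. In mRNA, 415 genes were higher and 539 lower in both Starved and E02H1.1 (311.7 and 273.1 from independent lists) and 398 opposite. With C27F2.4, 178 were higher and 42 lower in both (128.1 and 77.5) and 248 opposite. In footprints, 277 and 312 were shared with E02H1.1 (157.6 and 146.0) with 146 opposite, and 113 and 35 with C27F2.4 (73.4 and 32.97) with 64 opposite. In TE, Starved and C27F2.4 shared 4 lower genes (2.06 from independent lists) and 6 went opposite ways. Numbers from independent lists were not computed for genes that went opposite ways, so these counts alone do not show whether opposite changes were many or few. Over all genes tested in both, the fold changes of Starved correlated with those of E02H1.1 at r = 0.10 in mRNA, 0.18 in footprints and 0.03 in TE and with those of C27F2.4 at -0.01, 0.11 and -0.04. The jackknife SEs over libraries were 0.11, 0.11 and 0.08, and 0.11, 0.15 and 0.07, so none lay beyond 2 SEs of 0. Without Starved 1 and Starved 5 the mRNA values were -0.05 and -0.13, and without Empty_vector C and C27F2.4 A that of footprints with C27F2.4 was -0.07.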

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

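Of the tests in this part, those on the libraries that stand apart and on leaving out libraries of Starved or Fed were chosen after the result was seen, and the bound for the timing test was tightened after its value was known. In 443 groups of 4 or 6 libraries, 14 (3.16%) had a highest or lowest library farther from the rest than Dixon's 95% critical value, where chance gives about 1 in 20. Of these, 4 fell on C27F2.4 A, 3 on E02H1.1 D and 2 on Empty_vector C.

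The knockdown changes, and in part the Starved changes, lay along an axis on which libraries of 1 group also differed. Empty_vector C is not the sole source of the E02H1.1 mRNA changes, since 4437 genes still passed without it, against 5393 with it. C27F2.4 A enters that comparison only through the shared estimate of spread, and 5721 genes passed without it and 4928 without both. Without both, the shared mRNA genes fell from 1685 to 1095, and C27F2.4 footprints turned from 533 higher and 227 lower to 317 and 358. A part of the C27F2.4 changes could rest on these libraries, although they were picked for lying far out along component 1. A candidate explanation is a difference in developmental timing between the collected worms, under which the first component within a group should track the change seen in the other knockdown: the lowest absolute r across genes was 0.304 and the highest 0.51 between knockdowns, with 0.12 to 0.537 on leaving out 1 library of the group. The axis within Starved, which shares no library with the knockdowns, gave 0.68 with E02H1.1 and 0.54 with C27F2.4 in mRNA (at least 0.58 and 0.46 with 1 library left out) and that within Fed 0.02 and 0.04, but in footprints Starved gave 0.34 and 0.35 (at least 0.19 and 0.25) and Fed 0.19 and 0.26. With the Starved changes, the axes within Empty_vector, C27F2.4 and E02H1.1 gave 0.41, 0.32 and 0.04 in mRNA and 0.46, 0.34 and 0.21 in footprints, so timing stays open for both experiments, as does a direct effect of either knockdown.

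Other values far from their group were these. C27F2.4 A stood above the other 3 C27F2.4 libraries in 2 pharyngeal myosin genes: myo-2 at 171 CPM of mRNA against 135 to 140 CPM and 129 CPM of footprints against 72.9 to 79.3 CPM, and myo-1 at 118.5 CPM of mRNA against 92.2 to 94.3 CPM. E02H1.1 D had 22.4 M mRNA-seq counts against 19.2 to 19.7 M in the other E02H1.1 libraries. The set-25 mRNA of Starved 5 was at 38.6 CPM against 46.5 to 49.8 CPM in the other Starved libraries. In mRNA, puf-5 was at 18.7 CPM in E02H1.1 D against 22.5 to 23.2 CPM, and rpl-4 at 1276 CPM in E02H1.1 C against 1347 to 1361 CPM. The mRNA of T14A8.2 was at 22.1 CPM in C27F2.4 A against 15.6 to 16.6 CPM. Footprints of wago-1 were at 167.8 CPM in Empty_vector C against 137 to 141 CPM, and those of myo-2 at 56.7 CPM in Empty_vector B against 45.9 to 47.2 CPM. Footprints of C27F2.4 were at 54.6 CPM in E02H1.1 B against 64.1 to 65.8 CPM. As log2 ratios of footprints to mRNA, syd-2 was at -2.12 in E02H1.1 A against -2.25 to -2.24, E02H1.1 at -0.33 in E02H1.1 D against -0.92 to -0.89, and ZK856.16 at 0.45 in Empty_vector C against 0.16 to 0.21.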

How the results depend on the processing

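Most values held under the alternatives run: of 4972 values of 232 gene results, 4746 kept their direction and side of the threshold, 213 fell short of the threshold, 12 changed sign without passing either way and 1 reversed. The reversal was TE of mdt-15 in C27F2.4, at -0.31 and at 0.11 on the deposited TE values, which carry no scaling for library size. Most of these genes were named because they passed the threshold in the main fit, so the share that stayed past it was partly set by that choice. Of the values that kept direction and side, 2646 came from leaving out 1 library, which reuses most of the data. Counts over all genes moved more often, as given below. Library totals, deposited TE values less the library median, and leaving out Starved 1 and 5 or Empty_vector C and C27F2.4 A were chosen after seeing the data. Unless an alternative's own construction shows it, the cause was not tested. Ribo-seq libraries held 3.91 to 11.7 M counts, and every gene of that table had at least 10 counts in at least 13 libraries. Footprints and TE therefore say nothing of rarer transcripts or of genes read in few libraries, and F08G2.5 is not among the Ribo-seq genes.

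Asking for a fold of at least 1.5 as well left 290, 1391, 544 and 67 genes in mRNA (Starved, E02H1.1, C27F2.4, and E02H1.1 against C27F2.4), 151, 568, 353 and 36 in Ribo-seq and 38, 146, 23 and 2 in TE, since small changes are then not counted. Thinned counts, which hold fewer reads, gave 1752, 3333, 977 and 237 genes in mRNA, 493 in Ribo-seq of C27F2.4, and overlaps of 867 in mRNA and 403 in Ribo-seq. The DESeq2 Wald test gave 908 genes in mRNA of E02H1.1 against C27F2.4, 290 in TE of C27F2.4, 49 in TE of E02H1.1 against C27F2.4, a TE overlap of 253, and 8 and 5 lists in TE of E02H1.1 and C27F2.4; DESeq2 size factors gave 7 lists in TE of E02H1.1. Fitting only the 2 groups compared gave 699 genes in mRNA of E02H1.1 against C27F2.4, and voom 3 in its TE.

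The labels do not say that libraries of 2 groups with the same number or letter share anything else, and whether they share a day or culture stays open: they correlated at -0.25 to 0.45, and in no comparison did every library correlate best with its own. With the replicate block all the same, 1446 genes passed in mRNA of E02H1.1 against C27F2.4, 1343 in Ribo-seq of C27F2.4, 430 in Ribo-seq of E02H1.1 against C27F2.4, 268 in TE of C27F2.4 and 52 in TE of E02H1.1 against C27F2.4. The overlaps under it were 1075 in Ribo-seq and 235 in TE, with 7 lists in TE of E02H1.1. With cultures as the block, TE gave 1145, 2227, 662 and 260 genes for the 4 comparisons, an overlap of 529 and 8 lists for E02H1.1, and the call for the endoplasmic reticulum and mitochondrial unfolded protein response in TE of Starved did not pass (adjusted p = 0.0565, and 0.0574 with the replicate block).

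On the deposited TE values, 62, 759, 1184 and 10190 genes passed for Starved, E02H1.1, C27F2.4 and E02H1.1 against C27F2.4; less the library median, 31 and 10 passed for the last 2. Without Empty_vector C and C27F2.4 A, E02H1.1 against C27F2.4 gave 2649 genes in mRNA, 929 in Ribo-seq and 54 in TE, TE of C27F2.4 gave 236, the overlaps were 1095 in mRNA and 210 in TE, and the Ribo-seq correlation of Starved with C27F2.4 was -0.0713. Without Starved 1 and 5 the mRNA correlations of Starved were -0.0511 with E02H1.1 and -0.13 with C27F2.4, and with no filter the former was -0.0035. With an estimated correlation, 3, 0 and 1 of 17, 15 and 12 lists held in mRNA (Starved, E02H1.1, C27F2.4), 1, 1 and 1 of 15, 15 and 16 in Ribo-seq and 1, 1 and 0 of 14, 4 and 3 in TE.

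Leaving out 1 library at a time, the counts ran as follows. In mRNA, 1189 (without C27F2.4 B) to 1980 (C27F2.4 C) genes passed for C27F2.4 and 84 (E02H1.1 B) to 1713 (C27F2.4 A) for E02H1.1 against C27F2.4. In Ribo-seq, 482 (Empty_vector C) to 778 (C27F2.4 C) passed for C27F2.4 and 69 (E02H1.1 B) to 413 (C27F2.4 A) for E02H1.1 against C27F2.4. In TE, 422 (Starved 5) to 746 (Starved 1) passed for Starved, 594 (E02H1.1 B) to 1368 (C27F2.4 A) for E02H1.1, 9 (C27F2.4 C) to 227 (C27F2.4 A) for C27F2.4 and 1 (E02H1.1 B or C) to 20 (Empty_vector C) for E02H1.1 against C27F2.4. The overlap of E02H1.1 and C27F2.4 held 1115 (C27F2.4 B) to 1818 (C27F2.4 C) genes in mRNA, 378 (Empty_vector C) to 636 (C27F2.4 C) in Ribo-seq and 8 (C27F2.4 C) to 197 (C27F2.4 A) in TE. Gene lists in TE numbered 3 to 10 (E02H1.1 D) for E02H1.1 and 0 (Empty_vector C) to 6 (C27F2.4 A) for C27F2.4.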

Other observations

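Of the tests in this part, those on recovery of transcripts and on random lists for ribosomal protein mRNA, on regrouping libraries for ribosomal proteins, on adult markers, and on all gene families were chosen after the result was seen. Families were formed from gene names with at least 10 members, which gave 103 to 131 families per comparison, and only mrps in mRNA of C27F2.4 passed 0.05. Families named here were picked by hand. In mRNA of E02H1.1, the higher genes included neuropeptides of the flp family (19 of 28, median 0.66), receptors of the npr family (19 of 40, median 0.54), potassium channels of the twk family (21 of 38, median 0.52) and guanylate cyclases of the gcy family (13 of 26, median 0.41), but none of these families passed (adjusted p = 0.320 for each when the correlation between members was estimated). Mitochondrial ribosomal proteins of the mrps family were lower in mRNA of E02H1.1 (15 of 29, median -0.19, adjusted p = 0.0922) and of C27F2.4 (7 of 29, median -0.14, adjusted p = 0.0210). Of the proteasome regulatory subunits of the rpn family, 12 of 13 were lower in mRNA of E02H1.1 (median -0.24, adjusted p = 0.345). In footprints of Starved, nuclear pore genes of the npp family (18 of 24 lower and 1 higher, median -0.23) and splicing genes of the prp family (11 of 13 lower, median -0.17) were lower, each with an adjusted p of 0.548.

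In Starved, mRNA of cytosolic ribosomal proteins was higher (list median 0.27) and TE of the same genes lower (list median -0.18), but neither call held with an estimated correlation (adjusted p = 0.147 and 0.471). Of 10000 random lists matched for expression, 0 lay as far in mRNA and 0 in TE, which leaves out that members vary together. Within that limit they argue against expression level alone. Over all 462 splits of the libraries, which keep this, 1 lay as far in mRNA and 12 in TE, the real one included. These shares do not allow for the choice of this list among those tested, so chance stays open in TE. In mRNA only the real grouping lay as far, which makes chance alone less likely, but the same limit holds and chance is not excluded. An effect of Starved 1 and 5 alone is argued against (mRNA median 0.22 without both). Recovery of these transcripts in the mRNA-seq libraries alone cannot be told apart: their Ribo-seq list median lay 0.0922 above that of all genes, and at 0.10 outside 95% of random-list medians (-0.06 to 0.04), but a share of 0.258 of the 462 splits lay as far. For TE, the 36 members that varied least had a median of -0.15 and the 37 that varied most -0.24, and although -0.15 passed the bound set beforehand from random lists, 39 of 462 splits lay as far for these 36. A test by other library scalings was dropped because scaling moves all genes alike, and whether the worms changed translation of these mRNAs stays open.

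All 48 samples carry a young adult stage label, yet mRNA of 38 adult markers (6 vitellogenins, col-19 and 31 major sperm protein genes) summed to at most 5.99 CPM in any library. In the same libraries 7 sheath and cuticle markers listed as embryonic, picked after their abundances were seen, summed to 9102 to 11050 CPM. Of the 7, sqt-3 and dpy-17 had the highest means (3764 and 3019 CPM). Low capture of transcripts as a whole is argued against, since at least 81.7% of the genes of the table were detected in each library. A hypothesis is that the label describes the parents and the material was embryos, which was not tested here beyond the 5.99 CPM of adult markers. Markers that tell embryos from larvae were not examined, so larvae are not set aside.

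Whether chance alone could give the counts was asked by regrouping the libraries of both groups, with 100 of the 462 possible splits for Starved and all 35 for each pair of knockdown groups. Chance alone is made unlikely in Starved for mRNA (2915 genes, highest other split 817), Ribo-seq (3033, 672) and TE (665, 4). The same holds in E02H1.1 for mRNA (5393, highest other 0), Ribo-seq (2146, 0) and TE (1160, 0). It also holds in C27F2.4 for mRNA (1864, 34), Ribo-seq (760, 21) and TE (94, 0), although 9 genes passed in that TE comparison without C27F2.4 C. With so few splits, chance cannot be given a share under 1 in 100 for Starved or 1 in 35 for the knockdowns. Between E02H1.1 and C27F2.4 it cannot be excluded for mRNA (445; 644) or Ribo-seq (134; the highest other 33 above it), both highest with C27F2.4 A beside E02H1.1 A, B and D; for TE the real grouping called the most by a margin of 1 gene (5; 4), while leaving out 1 library gave 1 to 20. For gene lists, regrouped only against Fed or Empty_vector, chance cannot be excluded in any of the 9 comparisons. In Starved 17 lists passed against a highest other of 20 in mRNA, 15 against 19 in Ribo-seq and 14 against 16 in TE. The counts were 15 against 16, 15 against 15 and 4 against 7 in E02H1.1. They were 12 against 17, 16 against 18 and 3 against 10 in C27F2.4. Other splits put a median of 10, 9 and 5 lists past the threshold in Starved. These medians were 8.5, 10 and 2 in E02H1.1 and 9.5, 11 and 2 in C27F2.4. Passing camera with the preset correlation is thus common when these libraries are regrouped, and its p-values alone are weak evidence for a list.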
